A study of Rattus norvegicus and Mus musculus with 22 samples.

How the data were processed

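RNA-seq counts per gene were used for 22 samples, 12 of rat whole lung, 4 of rat lung CD4-positive cells and 6 of mouse splenic CD4-positive cells. The authors deposited raw counts, 1 column per sample and replicates not pooled, and per the file headers each column holds total counts per gene. The values are whole numbers that sum to a different total in each column, as raw counts do. Each of the 3 rat tables lists 22081 gene symbols and the mouse table lists 25683. The day 7 and day 56 lung tables share 20230 symbols. Per the submitters' processing notes the genome build was GRCm38 for all samples, a mouse build that is named for the rat samples too. The aligner, the counter, their versions and the annotation are not given in the sources used here. Per the labels, RNA was extracted with Trizol and a column kit with DNase and sequenced as Illumina libraries, lung CD4 cells were isolated by MACS and splenic cells by FACS. All 22 sample columns were matched to their labels by name, with 0 unmatched.

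Total counts per library ran from 8737138 to 23590070. A gene with 0 counts in a library is bounded by 3 counts, which is 0.343 CPM in the library with the fewest counts. Such floors and intervals cover counting error only.

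Groups followed the labels: genotype, day, tissue and tdTomato fraction. The comparisons were IL6KO against WT in day 7 lung, day 56 lung and day 7 lung CD4 cells, tdTomato-positive against tdTomato-negative splenic CD4 cells, the genotype by day interaction over the 12 lung libraries, and day 56 against day 7 in WT lung within the same fit. A positive log2 fold change is higher in IL6KO, in tdTomato-positive cells or at day 56. The tests, the gene lists, the fixed genes, the rule for naming genes and the alternatives were set before the data were examined, except where the text says otherwise.

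Counts were filtered with filterByExpr on the groups tested, scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3. The adjusted p of a single gene is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested in that comparison, and a gene was called at an adjusted p under 0.05. CPM given with an SD are TMM-scaled, and SE is the standard error of the log2 fold change. The genes named were the fixed genes, the called genes with the largest changes whose replicates did not overlap between the groups, with a mean of at least 1 CPM and without predicted or clone-based names, and up to 4 members of each list by smallest p. In day 56 lung and spleen, where fewer than 5 genes were called per direction, the 5 with the smallest p stood in. 1 gene with a large change is not reported here, and the totals include it.

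The 35 gene lists, written by hand, cover cytokine signaling, T cell states, other blood cells, vascular and epithelial cells, heart muscle, growth programs and measures of RNA quality. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with a correlation estimated from the data and fry. Members were counted over all genes and adjusted over the list alone. Some genes sit in more than 1 list. Overlaps of calls were tested with one-sided Fisher's exact tests against the product of the list sizes over the genes tested in both.

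Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter on low counts, a mean of at least 5 CPM, a log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Other splits of the samples into groups of the same sizes were refitted, all 10 for 3 against 3 and 40 for the interaction, 39 drawn and the real one. Splenic fractions with the same number came from the same mouse by their labels. The deviations of these fractions from their group means correlated at 0.03, 0.17 and 0.13 across genes, and the Y-linked gene Ddx3y had counts in both fractions of mouse 1 (2229 and 1155) and 0 in the other 4 libraries. WT and IL6KO rat samples of the same number differ in genotype, so they are not the same animal, and no label says whether whole-lung and CD4 samples share rats.

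The fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. In simulated day 7 lung 86.7% of genes changed by 1 on the log2 scale and 99.0% of those changed by 2 were recovered, with 3.68% of calls false. The shares were 63.6% and 90.0% for day 56 lung (6.71% of calls false), 70.4% and 95.0% for lung CD4 cells (11.8% false) and 72.7% and 90.8% for spleen (5.29% false). For the interaction they were 63.6% and 90.9% and for the days in WT 73.7% and 93.0%.

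Mouse gene positions come from GENCODE annotation of GRCm38 and count from 1. For rat genes the GRCr8 RefSeq gene table served only for which genes neighbour each other, matched by symbol for 94.3% of the 11986 genes tested in both day 7 comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main fits, and no pair of libraries of a group was a duplicate.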

Results

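RNA was sequenced from 22 samples and counted per gene in 4 tables. The 16 rat libraries came from the Sugen-hypoxia model of pulmonary hypertension, in which an inhibitor of the VEGF receptor is given together with low oxygen. Wild-type (WT) rats were compared with rats lacking Il6 (IL6KO), the gene of the inflammatory cytokine interleukin 6. Whole lung was taken at day 7 and at day 56, with 3 libraries per genotype and day. CD4-positive cells isolated from lung by MACS (magnetic sorting) at day 7 gave 2 libraries per genotype. The other 6 libraries came from 3 mice with an SM22alpha-Cre driver and the Ai14 reporter, in which cells with a history of Cre activity are red through tdTomato. Splenic CD4-positive cells of each mouse were sorted by FACS into a tdTomato-positive and a tdTomato-negative fraction. Total counts per library ran from 15011692 to 23590070 in day 7 lung, from 14415060 to 22961232 in day 56 lung, from 11477533 to 12930732 in lung CD4 cells and from 8737138 to 12560401 in spleen. The labels number the rat samples but do not say that they are separate animals, so the errors below hold between these samples.

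Il6 itself was near the lower end of detection in the lung. Day 7 lungs held 5, 11 and 6 Il6 counts in WT and 8, 5 and 2 in IL6KO. Day 56 lungs held 6, 6 and 5 counts in WT and 0, 2 and 3 in IL6KO. Lung CD4 isolates held 48 and 20 counts in WT and 8 and 17 in IL6KO, a log2 fold change of -1.41 (SE 0.62) that did not pass adjustment in edgeR (adjusted p = 0.234). No label says which part of Il6 is missing, and a transcript can persist beside a deletion, so these counts check the genotypes only weakly. The 6 spleen libraries held 0 Il6 counts each.

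The day 7 lung comparison asked which genes depend on IL-6 early in the disease. Lists of cytotoxic lymphocyte genes lay higher without IL-6, while lists of dividing cells, extracellular matrix and mast cells lay lower. They passed at a preset correlation between genes, and none passed with an estimated one (adjusted p = 0.434 for each but the mast cell list, at 0.603). Prf1, which encodes the pore-forming protein perforin, rose from 22.1 ± 4.61 to 57.7 ± 6.76 CPM (counts scaled to library size; SD, n = 3 each), a log2 fold change of 1.38 (SE 0.15, adjusted p = 0.00349 in edgeR). Ccl5, a chemokine gene of activated T and natural killer (NK) cells, rose by 1.24 on the log2 scale (SE 0.13, adjusted p = 0.00227), and Tbx21, the Th1 transcription factor gene, by 1.06 (SE 0.13, adjusted p = 0.00661). Socs3, a feedback inhibitor switched on by STAT3 when IL-6 engages its receptor gp130, fell by 0.80 (SE 0.13), from 19.4 ± 1.63 to 11.1 ± 1.47 CPM (adjusted p = 0.0178). The Socs3 call ended without WT library 2 (adjusted p = 0.0723) and without IL6KO library 2 (adjusted p = 0.0563). The receptor genes Il6r (0.31, adjusted p = 0.143) and Il6st (0.18, adjusted p = 0.571) and Stat3 (-0.14, adjusted p = 0.426) were not called.

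In all, edgeR called 300 of 14368 genes in day 7 lung, 134 higher and 166 lower in IL6KO, and 104 of these changed by at least 1 on the log2 scale. The largest rise among the named genes was in C5, which encodes complement component 5. C5 went from 1.84 ± 1.25 to 56.5 ± 5.42 CPM (log2 fold change 4.96, SE 0.31, adjusted p = 0.000906). At day 56, C5 varied widely between the WT lungs (values in the closing paragraph), so it also differs between libraries of the same genotype. Cd300lg, an endothelial surface receptor gene, rose by 4.31 (SE 0.45), and Prox2, a homeobox gene, by 4.16 (SE 0.35) from 0.184 ± 0.115 CPM. Adamts13, which encodes the protease that trims von Willebrand factor, fell by 3.73 (SE 0.21), from 16.2 ± 1.15 to 1.20 ± 0.439 CPM (adjusted p = 0.000109). Asb15 fell by 3.64 and Drp2 by 2.63. Each of these 6 genes kept its call in every alternative that tested it. Of 49 called genes examined singly at day 7, 22, 27 and 22 lost the call without WT 1, 2 and 3, and 30, 30 and 13 without IL6KO 1, 2 and 3.

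Fixed gene lists were used to describe the day 7 changes by cell type and program. The number of lists that passed does not set the genotypes apart. The real split passed 12 lists, and another split of the same libraries passed 14. Of 16 Th1 and cytotoxic genes, 7 rose and 0 fell over all genes, and 9 rose when adjusted over the list alone (median log2 fold change 0.99, camera adjusted p = 2.51e-10; adjusted p = 0.434 with an estimated correlation). Of 10 NK cell genes, 6 rose by either count (median 1.09, adjusted p = 1.64e-07; adjusted p = 0.434 with an estimated correlation). Granzyme A (Gzma, log2 fold change 1.72, SE 0.18) was among the called Th1 and cytotoxic genes, although granzyme genes are close copies whose reads counting can divide. T cell identity genes such as the CD3 subunits had 0 of 18 called (median 0.20, adjusted p = 0.0532), and the Th17, Treg, Th2, Tfh, naive T cell and T cell activation lists had 0 called members as well. Of 28 proliferation genes, 8 fell over all genes and 22 when adjusted over the list alone (median -0.49, adjusted p = 2.59e-18; adjusted p = 0.434 with an estimated correlation). Ccnb1, the mitotic cyclin B1 gene, fell by 0.76 (SE 0.11) from 16.6 ± 0.770 to 9.76 ± 0.854 CPM. Of 31 extracellular matrix genes, 6 fell over all genes, and adjusted over the list alone 9 fell and 1 rose (median -0.26, adjusted p = 3.44e-08; adjusted p = 0.434 with an estimated correlation).

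Acute phase genes, which liver and inflamed tissue make under IL-6, moved both ways in day 7 lung. Of 13 tested, 2 fell and 1 rose over all genes, and 7 fell and 1 rose when adjusted over the list alone (median -0.45, adjusted p = 4.52e-06; adjusted p = 0.434 with an estimated correlation). Fgg, the fibrinogen gamma chain gene, fell by 0.78 (SE 0.095). The 2 fallen mast cell and eosinophil genes of 10 included Tpsb2, a mast cell tryptase gene (-1.50, SE 0.22), and adjusted over the list alone 5 fell and 1 rose (median -0.96, adjusted p = 0.0101; adjusted p = 0.603 with an estimated correlation). Of 20 smooth muscle contractile genes, 2 fell over all genes and 5 when adjusted over the list alone (median -0.09, adjusted p = 0.000703; adjusted p = 0.434 with an estimated correlation). Platelet genes stood higher, with 0 of 13 called over all genes and 6 higher when adjusted over the list alone (median 0.50, adjusted p = 0.00175; adjusted p = 0.434 with an estimated correlation). B cell genes (0 of 17 called, median 0.31, adjusted p = 0.0396), airway epithelium genes (1 of 18 higher, median 0.13, adjusted p = 0.0450) and ribosomal protein genes (1 of 68 higher, median 0.09, adjusted p = 7.38e-07) also lay higher. Macrophage genes lay lower (1 of 25 lower, median -0.22, adjusted p = 0.0492). Each of these last 4 lists had adjusted p = 0.747 with an estimated correlation. The IL-6 and STAT3 pathway list had 1 of 27 genes higher (Lifr) and 1 lower (Socs3), with a median of -0.10 (adjusted p = 0.352). The Lifr call in edgeR ended without WT 2 (adjusted p = 0.0911), WT 3 (0.0617), IL6KO 1 (0.0737) and IL6KO 2 (0.0753).

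In total 12 of 34 tested lists passed at day 7, and the other 22 had adjusted p between 0.0532 and 0.938. With a correlation estimated from the data none passed. In fry, which asks whether a list's genes move 1 way on balance, smooth muscle alone did (adjusted p = 0.0106). The Th17 list had a median of -0.09 beside a mean of 0.01, the pericyte list a median of 0.01 beside a mean of -0.10, and the neutrophil list a median of 0.02 beside a mean of -0.06. The MHC class II list had a median of -0.05 and a mean of -0.06 beside a test direction of higher. None of these 4 lists passed. Leaving out 1 library changed the number of called genes to 195, 115 and 154 without WT 1, 2 and 3, and to 97, 94 and 372 without IL6KO 1, 2 and 3.

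**Figure D1:**
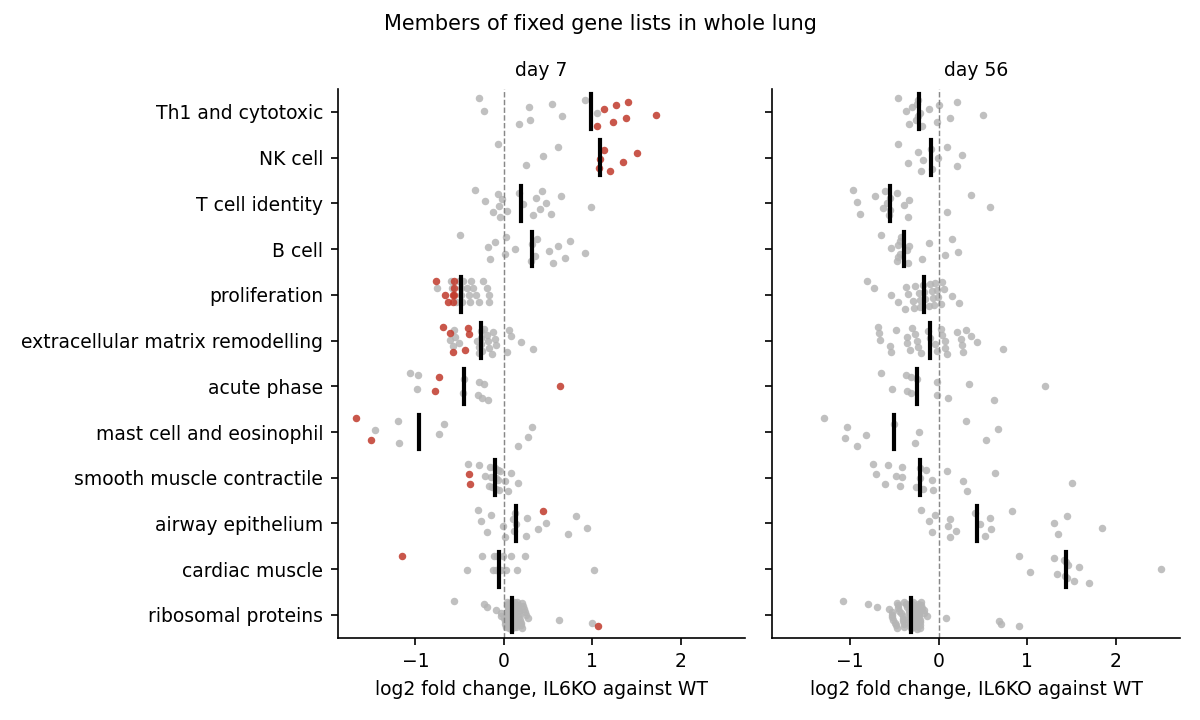
Log2 fold changes (IL6KO against WT) of the members of 12 fixed gene lists in whole lung at day 7 (left) and day 56 (right). Each point is 1 gene, red where edgeR called it over all genes, and the black bar is the median of the list. Th1 and NK cell genes lie to the right at day 7 (medians 0.99 and 1.09) and around 0 at day 56 (medians -0.22 and -0.08).

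At day 56, when the vascular disease of this model is advanced, 2 genes differed between the genotypes. Ephx2 encodes soluble epoxide hydrolase, which breaks down vasodilating epoxy fatty acids, and fell by 2.99 (SE 0.14), from 19.1 ± 0.641 to 2.39 ± 0.265 CPM (SD, n = 3 each, adjusted p = 0.00142). Slpi, a secreted inhibitor of leukocyte proteases, fell by 3.08 (SE 0.23), from 10.8 ± 2.00 to 1.27 ± 0.206 CPM (adjusted p = 0.0142). Without WT library 2 or any 1 of the IL6KO libraries, Slpi was no longer called (adjusted p = 0.0710 without WT 2, and 0.123, 0.143 and 0.0802 without IL6KO 1, 2 and 3). Adamts13 was again lower (-2.97, SE 0.32) but not called by edgeR with all libraries (adjusted p = 0.0610). It was called by DESeq2 (adjusted p = 8.34e-15), without the filter on low counts (0.0264), without WT 1 (0.0194) and without WT 3 (0.0103). Socs3 was not called (0.53, SE 0.15, adjusted p = 0.401), nor were Il6r (0.07, adjusted p = 0.901), Il6st (0.34, adjusted p = 0.488) and Stat3 (-0.05, adjusted p = 0.803).

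Of the 13 fixed lists that passed at day 56, the airway, platelet, proliferation and smooth muscle lists had also passed in the same direction at day 7, and the B cell and ribosomal lists in the opposite one. Cardiac muscle genes stood higher in IL6KO (0 of 13 called, median 1.44, adjusted p = 2.22e-07). Their mean log2 of CPM + 1 was 1.29, 2.73 and 4.26 in WT 1, 2 and 3, so WT 3 lay within the IL6KO range of 3.86 to 4.87. Airway epithelium genes were higher too, 3 of 18 when adjusted over the list alone (median 0.44, adjusted p = 1.50e-05). T cell identity genes stood lower (1 of 17 when adjusted over the list alone, median -0.55, adjusted p = 0.000197), with Cd3e at -0.97 (SE 0.20). Ribosomal protein genes were lower with 0 of 73 called (median -0.31, adjusted p = 1.69e-17). Lower medians were also found for B cell genes (-0.39, adjusted p = 0.0185), smooth muscle genes (-0.21, adjusted p = 0.0185), Tfh genes (-0.30, adjusted p = 0.0212) and proliferation genes (-0.17, adjusted p = 0.0212). MHC class II genes (-0.27, adjusted p = 0.0270), plasma cell genes (-0.31, adjusted p = 0.0316) and chemokines (-0.26, adjusted p = 0.0370) were lower too. Platelet genes (median 0.25, adjusted p = 0.0373) and erythroid genes (median 0.61, adjusted p = 0.0455) were higher. All 13 of these lists had adjusted p = 0.737 with an estimated correlation, and none passed in fry, where the lowest adjusted p was 0.285. Another split of the same libraries passed 23 lists. The IL-6 and STAT3 pathway list had 0 of 26 genes called (adjusted p = 0.776). That list had a median of 0.00 beside a mean of -0.09, the T cell activation list a median of -0.00 beside a mean of 0.03 and a test direction of lower, and the neutrophil list a median of -0.07 beside a fry direction of higher.

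The day 56 counts depended on single libraries and on the tool. Of 14475 genes tested, 1649 had an unadjusted p under 0.05 in edgeR, against the 2 called. DESeq2 called 178 genes (101 higher, 77 lower) and limma-voom 4 (1 higher, 3 lower). Without WT library 3, edgeR called 1268 genes, 793 higher and 475 lower. On the first principal component, which held 47.5% of the variance, WT libraries 1 and 2 lay at -34.7 and -28.1, while WT library 3 lay at 14.2 beside the IL6KO libraries at 16.9, 12.5 and 19.3. Without WT 1 the count was 4, and without WT 2 or IL6KO 2 it was 1. The number of lists that passed fell from 13 to 7 without WT 1, 4 without WT 3 and 8 without IL6KO 1.

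**Figure D2:**
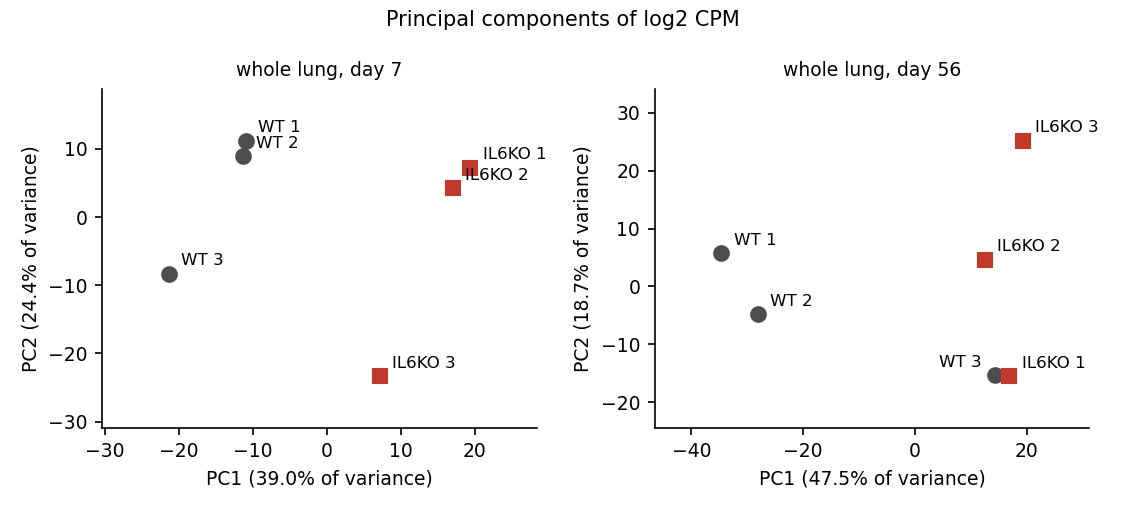
First and second principal component of log2 CPM for the 6 whole-lung libraries of day 7 (left) and of day 56 (right), WT as grey circles and IL6KO as red squares. At day 56, WT 3 lies at 14.2 on the first component, among the IL6KO libraries.

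Whether the effect of IL-6 loss changed between the days was tested as a genotype by day interaction over the 12 lung libraries. Of 4 genes fixed beforehand, Socs3 passed only when adjusted over these 4, an adjustment narrower than the rule for calls. Its IL6KO effect was 1.33 higher at day 56 than at day 7 (SE 0.20, edgeR adjusted p = 0.000105 over the 4 genes). Over all genes Socs3 was not called (edgeR adjusted p = 0.122). Il6r (-0.24), Il6st (0.16) and Stat3 (0.09) each had adjusted p = 0.515 over the 4. Of 34 lists, 13 passed, 5 upward and 8 downward. The IL6KO effect was lower at day 56 than at day 7 for Th1 and cytotoxic genes (median difference -0.92, camera adjusted p = 8.57e-13) and NK cell genes (median difference -1.13, adjusted p = 1.12e-06). None of the 13 passed with an estimated correlation (lowest adjusted p = 0.491). Over single genes, edgeR called 0 of 13865, with 1043 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 48. Without WT day 56 library 3 edgeR called 597, Socs3 among them (adjusted p = 0.00868), and without IL6KO day 56 library 3, WT day 7 library 1 or IL6KO day 7 library 2 it called 1, 2 and 1.

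In WT rats alone, day 56 was set against day 7. No untreated lung was sequenced on either day, so the course of the disease cannot be told apart from age. Cell division and matrix genes were far lower late. Of 28 proliferation genes 26 fell and 0 rose (median -1.80), and of 30 extracellular matrix genes 23 fell and 0 rose (median -1.23). Mki67, the gene of a nuclear protein of cycling cells, fell by 1.67 (SE 0.15), Top2a by 2.16 (SE 0.13), Col1a1, a collagen gene, by 2.11 (SE 0.17) and Acta2, the smooth muscle actin gene, by 0.80 (SE 0.13, adjusted p = 0.00135). These 4 genes were chosen after their values were seen. Lymphocyte lists moved unequally, and lists were counted but not tested between the days. Rises were called for 13 of 16 Th1 and cytotoxic genes (median 1.41), 13 of 16 B cell genes and 7 of 11 NK cell genes (median 1.52), with 0 falls. T cell identity genes had 5 of 17 higher over all genes and 13 when adjusted over the list alone (median 0.77). Tfh genes had 4 of 13 higher and 1 lower (median 0.92), T cell activation genes 5 of 20 and 1 (0.41), naive T cell genes 3 of 13 and 1 (0.21) and plasma cell genes 2 of 9 and 1 (0.13). Th2 genes had 1 of 9 higher and 1 lower (-0.04), Treg genes 4 of 18 higher (0.04) and Th17 genes 0 of 10 called (0.15). Of 11 erythroid genes 9 fell (median -2.53), and of 20 smooth muscle genes 9 fell. Il6r rose by 0.72 (SE 0.18, adjusted p = 0.0188), a call that ended without WT day 56 library 1 (0.0548), WT day 7 library 1 (0.0745) and WT day 7 library 3 (0.0528), and Socs3 was not called (-0.29, adjusted p = 0.198).

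The day comparison also compares 2 count tables. In total 2048 of 13865 genes were called between the days, 932 higher and 1116 lower at day 56. Among the called genes were 58 that were over 10 CPM in all 6 libraries of 1 day and under 1 CPM in all 6 of the other, genotype aside. Rpl8, a housekeeping ribosomal protein gene, had 0 counts in each day 7 library and 442 to 660 CPM at day 56, and Pak2 and Ndufa1 had 0 at day 7 too. Rpl8 and Ndufa1 also had 0 counts in each day 7 CD4 library, which argues against a change of lung tissue as the reason for both. For the other called genes day and table cannot be told apart. This also touches the 41 of 68 ribosomal protein genes called higher at day 56. Without the 58 genes 1966 calls were made (886 higher, 1080 lower), an alternative added after the data were seen. Leaving out WT day 7 library 2 or 3 gave 1235 and 1308 calls, and leaving out WT day 56 library 1 or 3 gave 1324 and 3656.

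In lung CD4 isolates at day 7, Socs3 and Batf, which lie downstream of the IL-6 receptor, were lower without IL-6. Socs3 fell by 1.50 (SE 0.16), from 299 ± 48.1 to 106 ± 17.0 CPM (SD, n = 2 each, adjusted p = 0.00897), and stayed called in every alternative. Batf, a transcription factor gene that STAT3 activates in T helper cells, fell by 1.19 (SE 0.13), from 49.5 ± 7.23 to 21.7 ± 0.175 CPM (adjusted p = 0.00516). Socs1, a related feedback inhibitor gene, fell by 1.02 (SE 0.22, adjusted p = 0.0365). Il6r, the receptor gene, rose by 0.54 (SE 0.084, adjusted p = 0.0152). The Il6r call ended without WT 1 (adjusted p = 0.0959) and without WT 2 (0.115). The Socs1 call ended without WT 1 (0.239), WT 2 (0.0804) or IL6KO 1 (0.0548), and by DESeq2 (0.0510) and limma-voom (0.0652). Il6st (-0.06, adjusted p = 0.793) and Stat3 (-0.37, adjusted p = 0.0830) were not called. In the IL-6 and STAT3 pathway list, 1 of 25 genes rose and 3 fell over all genes, and 3 rose and 6 fell when adjusted over the list alone (median -0.10, adjusted p = 0.0414; adjusted p = 0.402 with an estimated correlation).

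**Figure D3:**
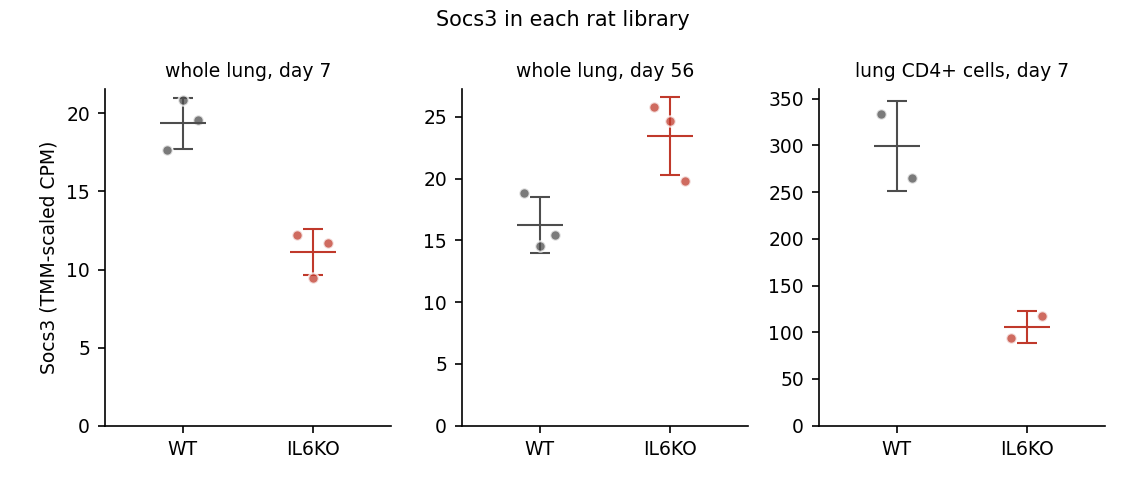
Socs3 in TMM-scaled CPM in each rat library (points), with the group mean (bar) and SD (whisker), WT in grey and IL6KO in red. IL6KO lies below WT in whole lung at day 7 (11.1 against 19.4) and in lung CD4 cells (106 against 299), and at day 56 the groups were not separated by the test (adjusted p = 0.401).

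Of the T cell lists, those of identity, regulatory, Th1 and naive T cells passed as lower in the IL6KO isolates. T cell identity genes fell in 4 of 19 cases over all genes, and adjusted over the list alone 13 fell and 1 rose (median -0.29, adjusted p = 1.99e-05; adjusted p = 0.391 with an estimated correlation). Cd3e fell by 0.41 (SE 0.082), while Cd4 itself was not called (0.27, adjusted p = 0.0832). The CD8 genes fell more, Cd8a by 3.23 (SE 0.19), from 113 ± 24.5 to 12.1 ± 1.58 CPM, and Cd8b by 1.60 (SE 0.22). Cd8a kept its call in every alternative that tested it, while Cd8b did not. Regulatory T cell genes had 4 of 19 lower over all genes, and adjusted over the list alone 6 lower and 1 higher (median -0.39, adjusted p = 0.0176; adjusted p = 0.391 with an estimated correlation). Th1 and cytotoxic genes had 4 of 17 lower by either count (median -0.26, adjusted p = 0.0139; adjusted p = 0.395 with an estimated correlation), with Il18rap, a receptor subunit for IL-18, down by 0.90 (SE 0.082). This is the opposite of their direction in day 7 whole lung. Naive T cell genes had 4 of 13 lower over all genes, and adjusted over the list alone 6 lower and 1 higher (median -0.34, adjusted p = 0.00241; adjusted p = 0.391 with an estimated correlation). Tfh genes had 2 of 13 lower over all genes (camera adjusted p = 0.0768, fry adjusted p = 0.0191). T cell activation genes (1 of 20 higher and 2 lower, median 0.21, adjusted p = 0.354), Th17 genes (1 of 12 lower, median -0.19, adjusted p = 0.390) and Th2 genes (1 of 7 higher, adjusted p = 0.882) did not pass. Of 28 proliferation genes 1 was higher and the list did not pass (adjusted p = 0.256).

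Markers of other cell types differed between the CD4 isolates as well. Macrophage genes had 6 of 25 higher and 0 lower by either count (median 0.56, adjusted p = 1.99e-05; adjusted p = 0.391 with an estimated correlation). Csf1r, the macrophage growth factor receptor gene, went from 894 ± 34.2 to 1522 ± 5.12 CPM, above Cd3e at 622 ± 13.1 and 469 ± 30.5. In rats, monocytes and macrophages also carry CD4. B cell genes had 2 of 14 higher over all genes and 8 when adjusted over the list alone (median 0.97, adjusted p = 0.000706; adjusted p = 0.391 with an estimated correlation; fry adjusted p = 0.0191), and erythroid genes 2 of 10 over all genes and 3 over the list alone (median 2.05, adjusted p = 5.80e-07; adjusted p = 0.391 with an estimated correlation). Lung tissue genes were lower. Alveolar epithelium genes had 8 of 18 lower over all genes, and adjusted over the list alone 11 lower and 1 higher (median -0.93, adjusted p = 3.30e-08), smooth muscle genes 3 of 14 and 9 (median -0.83, adjusted p = 1.15e-06) and airway genes 4 of 14 and 6 (median -1.30, adjusted p = 2.44e-05; fry adjusted p = 0.0191). Each of these 3 lists had adjusted p = 0.391 with an estimated correlation. Sftpb, a surfactant protein gene of alveolar type 2 cells, fell by 1.89 (SE 0.16). Endothelial genes (2 of 17 lower, median -0.35, adjusted p = 0.00494), pericyte genes (0 of 15 called, median -0.71, adjusted p = 0.0139) and neutrophil genes (3 of 13 lower, median -1.50, adjusted p = 0.00241) were lower, with adjusted p of 0.399, 0.391 and 0.399 with an estimated correlation. MHC class II genes had 2 of 12 higher (median 0.54, adjusted p = 0.00761; adjusted p = 0.402 with an estimated correlation).

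**Figure D4:**
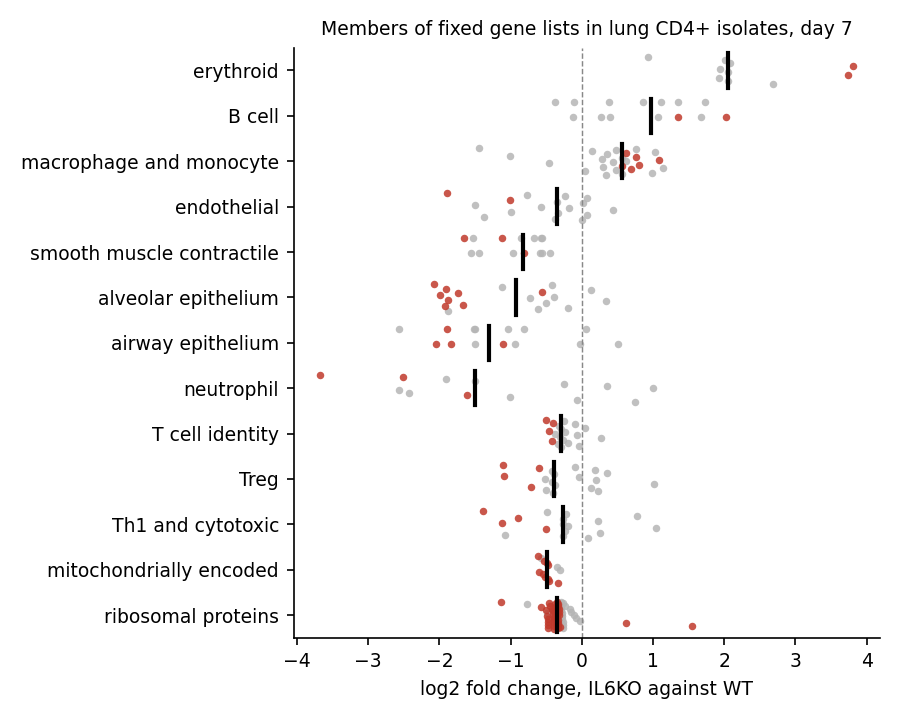
Log2 fold changes (IL6KO against WT) of the members of 13 fixed gene lists in lung CD4 isolates at day 7. Each point is 1 gene, red where edgeR called it over all genes, and the black bar is the median of the list. Macrophage, B cell and erythroid medians lie above 0 (0.56, 0.97 and 2.05) and alveolar, airway and neutrophil medians below 0 (-0.93, -1.30 and -1.50).

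The interferon response list lay higher in the CD4 isolates at the preset correlation (median 0.48, adjusted p = 1.99e-05), but not with an estimated one (adjusted p = 0.402) or in fry (adjusted p = 0.232). Over all genes 7 of 33 were higher, 1 was lower and 25 were not called. Adjusted over the list alone, 10 were higher and 1 lower. The lower one was Ifi27 (-1.30, SE 0.14). Stress genes of dissociated cells had 5 of 21 higher and 1 lower, Socs3 being the lower one (median 0.31, adjusted p = 1.99e-05; adjusted p = 0.391 with an estimated correlation). Ribosomal protein genes had 42 of 67 lower and 2 higher (median -0.34, adjusted p = 8.35e-26), and mitochondrially encoded genes 10 of 13 lower (median -0.49, adjusted p = 2.67e-11), each with adjusted p = 0.391 with an estimated correlation. Mitochondrial genes took 7.86% and 7.78% of counts in the WT libraries and 5.50% and 6.11% in the IL6KO libraries, and ribosomal protein genes 8.21% and 7.997% against 6.52% and 6.55%.

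Altogether edgeR called 784 of 12243 genes in the CD4 isolates, 428 higher and 356 lower, with 256 changing by at least 1 on the log2 scale (75 higher, 181 lower). Among the largest changes, Erp27, which encodes a chaperone of the endoplasmic reticulum, fell by 6.01 (SE 0.17), from 49.9 ± 0.178 to 0.763 ± 0.0251 CPM, Nefh by 4.60 (SE 0.36), Arhgef10 by 3.39 (SE 0.17) and Lcn2, a neutrophil and epithelial gene, by 2.51 (SE 0.14). RT1-CE1, a class I gene of the rat MHC, rose by 2.66 (SE 0.11), but the RT1 genes are a family of near copies among which reads can be divided. Dsg3 had 0 counts in both IL6KO libraries, at least 118-fold below WT against a floor of 3 counts over the group. Dsg3 also ran from 0 to 173 counts within the WT day 56 whole-lung libraries, so it varies between libraries of the same genotype. Of 28 tested lists 19 passed, 6 higher and 13 lower, and the other 9 had adjusted p between 0.0768 and 0.882. None passed with an estimated correlation, and 3 did in fry. The NK cell list had a median of 0.18 beside a mean of -0.06, and the Th2 list a fry direction of higher beside a median of -0.20. Of 68 called genes examined singly, 47 lost the call without WT 1, 46 without WT 2, 4 without IL6KO 1 and 7 without IL6KO 2. Without WT 1 edgeR called 76 genes and without WT 2 it called 115, fits in which the lone WT library is taken to vary like the IL6KO pair.

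The 3 IL6KO comparisons share no library, and the overlaps between their calls were tested. No label says whether CD4 and whole-lung samples came from the same rats, and if they did, the Fisher p values below would not compare independent samples. Day 7 lung and day 7 CD4 cells shared 17 higher genes, where independent lists would share 3.32 (one-sided Fisher's exact test, p = 2.57e-08), and 16 lower genes against 3.44 (p = 2.97e-07). A further 13 genes were called in opposite directions, for which no expected number was computed. The Fisher test takes every gene as equally likely to be called, so genes that are easily called can enlarge each overlap. Spearman's rho of the fold changes over the 11986 genes in both was 0.04, genes not being independent replicates. Socs3, Fgg, the tissue factor gene F3 and the gap junction gene Gja1 were among the genes lower in both, and C3, Angpt1 and S1pr5 among those higher in both. Day 7 and day 56 lung shared 0 calls in either direction by edgeR, day 56 having only Ephx2 and Slpi, while DESeq2 found 16 shared higher and 23 shared lower genes with 0 opposite, and rho over 13368 genes was 0.31. At an unadjusted p under 0.01 edgeR itself gave 38 higher and 37 lower genes in both, and 1 opposite. Day 56 lung and CD4 cells shared 0 calls by edgeR and 6 higher and 5 lower by DESeq2, which called 8 in opposite directions.

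The spleen comparison asked whether CD4 cells marked by the SM22alpha-Cre reporter differ from unmarked ones of the same mice. The spleen values come from the planned fit, which does not pair the fractions of a mouse, unless the mouse is named as a block. Tagln, the gene whose promoter is named SM22alpha (GRCm38 chromosome 9, 45929619 to 45936058, minus strand), stood at 2.54 ± 1.37 CPM in tdTomato-positive and 2.56 ± 1.14 CPM in tdTomato-negative cells (SD, n = 3 each; log2 fold change -0.01, SE 0.67, adjusted p = 1.00), so no difference was detectable. Acta2 was not called either (0.20, SE 0.87), nor were Il6ra (-0.11), Il6st (0.04), Stat3 (0.17) and Socs3 (-0.22), each with adjusted p = 0.998. The IL-6 and STAT3 pathway list (0 of 25 called, adjusted p = 0.328), the T cell identity list (0 of 19, adjusted p = 0.238) and the smooth muscle list (0 of 6, adjusted p = 0.549) did not pass. Exosc6, a gene of the RNA exosome (chromosome 8, 111056339 to 111057664, plus strand), had 0 counts in the 3 tdTomato-positive libraries and 156, 98 and 108 in the tdTomato-negative ones, at least 118-fold lower against a floor of 3 counts over the group (adjusted p = 0.00117). Its call ended without tdTomato-negative library 1 (adjusted p = 0.0768) and by limma-voom (0.0524). Whether reads of this gene were counted under a near-identical copy in some libraries was not tested.

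Genes of antigen-presenting cells stood higher in the tdTomato-positive fraction. MHC class II and dendritic cell genes had 0 of 15 called over all genes and 6 higher when adjusted over the list alone (median 0.82, adjusted p = 8.29e-15; adjusted p = 0.149 with an estimated correlation). B cell genes had 4 of 17 higher over the list alone (median 0.55, adjusted p = 7.07e-08) and macrophage genes 1 of 18 (median 0.50, adjusted p = 4.39e-05), both with adjusted p = 0.149 with an estimated correlation. Fcer2a, the CD23 gene of B cells, went from 3.57 ± 1.46 to 13.7 ± 3.46 CPM (log2 fold change 1.93, SE 0.39) and Csf1r from 6.24 ± 3.26 to 18.6 ± 0.716 CPM (1.56, SE 0.35), without passing adjustment over all genes in edgeR (adjusted p = 0.958 and 0.998). DESeq2 called Fcer2a (1.94, adjusted p = 0.0224). Smaller upward shifts passed for proliferation genes (median 0.28, adjusted p = 0.00450; 0.149 with an estimated correlation), Th1 genes (0.31, 0.00513; 0.433), plasma cell genes (0.45, 0.00785; 0.154) and Th17 genes (0.31, 0.0457; 0.268). Ribosomal protein genes (median -0.25, adjusted p = 6.55e-28; 0.433 with an estimated correlation), mitochondrial genes (-0.11, 0.00928; 0.571) and naive T cell genes (-0.10, 0.0188; 0.433) were lower.

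In the spleen edgeR called 1 of 11083 genes, Exosc6, with 395 at an unadjusted p under 0.05, while DESeq2 called 2 (Exosc6 and Fcer2a) and limma-voom 0. With the mouse as a block, which the shared animals call for, edgeR called 3 genes, 2 higher and 1 lower. The lower one was Exosc6, and the 2 higher ones were not among the genes examined singly. With the block 9 lists passed in place of 10, the Th17 list dropping out (adjusted p = 0.0567). No list passed in fry, where the lowest adjusted p was 0.202. The other 11 of 21 tested lists had adjusted p between 0.143 and 0.815, the stress list with a median of 0.01 beside a test direction of lower.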

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

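The tests of heart muscle, ribosomal share, T cell share, RT1 neighbours, carried-over tissue or cells among shared falls, the places over 284 genes and those of the IL6KO libraries were chosen only after the results were seen. All list results here rest on a preset correlation, and none passed with an estimated one.

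The difference in the effect of losing IL-6 between day 7 and day 56 was itself tested. Over all genes it passed for no gene. It passed for 1 fixed gene when adjusted over 4 fixed genes alone, and for 13 lists at the preset correlation only (lowest adjusted p = 0.491 with an estimated one). These lists were not refitted on other splits of the samples. The Socs3 effect was 1.33 higher on the log2 scale at day 56 (SE 0.20, edgeR adjusted p = 0.000105 over the 4 fixed genes, 0.122 over all genes). Below WT in each of the 3 IL6KO libraries at day 7, Socs3 lay above WT in each of the 3 at day 56. Median differences of lymphocyte lists were -0.92 for Th1 and cytotoxic genes (adjusted p = 8.57e-13), -1.13 for NK cells (1.12e-06), -0.76 for T cell identity (1.28e-07), -0.65 for Tfh (0.00410) and -0.60 for B cells (3.07e-05). The medians were -0.20 for MHC class II genes (0.0329), -0.25 for chemokines (0.00262) and -0.41 for ribosomal proteins (2.61e-28). Upward differences were 0.29 for proliferation (6.77e-05), 0.12 for extracellular matrix (0.0115), 0.14 for alveolar epithelium (0.0470), 0.32 for airway epithelium (0.000853) and 1.50 for cardiac muscle (1.37e-10). Each day is a separate count table, so genotype effects within a day are unaffected by table differences that act alike on both genotypes.

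In day 56 lung the library labelled WT 3 lies with the IL6KO libraries on the first component, and its removal raises the calls from 2 to 1268. A mislabelled IL6KO sample is argued against: between the other WT libraries (0) and IL6KO (1), WT 3 has a place of 0.2496 over the 33 genes called in both day 7 comparisons, the planned test (quartiles -0.03 to 0.41). This measure is loose, with a 95% interval of -0.74 to 0.69, WT 1 at 0.44 and WT 2 at -1.08. Over the wider set of 284 genes called at day 7 the place of WT 3 is -0.09 (95% interval -0.33 to 0.11). On these genes each IL6KO library, set against WT 1 and 2 and the other IL6KO libraries, lies at 0.846, 1.15 and 1.02 (lowest 95% limit 0.703). Heart muscle in the dissected tissue may contribute and stays open, since Myh6 reached 151 CPM in WT 3 and 108 to 257 CPM in IL6KO against 2.76 and 40.8 CPM in WT 1 and 2, yet WT 2, at 0.485 of the way on the cardiac list, sits at 0.134 on the component. RNA quality cannot be told apart either, as the ribosomal share of WT 3 (2.328%) lies just above the IL6KO range of 2.08% to 2.317% and below WT 1 and 2 (2.92% and 2.80%), and a difference among rats was not tested.

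In lung CD4 isolates Socs3 fell while markers of other cell types moved. Lung tissue carried over into the isolates, scaled by Sftpc at 11.3% in WT and 2.94% in IL6KO, would bring 0.965% of the Socs3 difference, which argues against it as the cause. A lower share of T cells alone would raise the other types alike and is argued against by neutrophil genes, with a median of -1.50 (quartiles -2.42 to -0.06), beside macrophage genes at 0.56 (quartiles 0.30 to 0.76). A change in the share of macrophages, which MACS for CD4 does not remove in rats, stays open. So does a lower response per T cell, which the design names through the genotype and which may underlie the fall of Socs3 and Batf. The neutrophil median of -1.50 lies close to the Socs3 log2 fold change of -1.50, and the T cell identity median was -0.29. Which cells of the isolates carried the Socs3 transcripts was not tested.

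Whole lung and CD4 cells at day 7 shared 33 calls of the same direction, beside 13 in opposite directions. Chance overlap of independent lists is argued against by the larger Fisher p of 2.97e-07. That test takes every gene as equally likely to be called, and the number of opposite calls was not tested. Whether the samples came from the same rats is not labelled, so rats in common stay open as a reason. Variants within 200 genes on either side of the Il6 deletion are argued against for the 28 shared genes matched by symbol, as 0 of them lie there. Only 47 tested genes lie in that stretch, too few for the Fisher test to show a lack (one-sided Fisher's exact p = 1). Variants farther away were not tested, apart from the RT1 stretch below. Whole-lung tissue carried over at the 11.3% of Sftpc is argued against for the 16 shared falls: 31 smooth muscle and endothelial genes stood in the WT isolates at a median of 1.85% of their whole-lung level (quartiles 1.47% to 3.67%), and 7 of the 16, Gja1 among them, would exceed their whole level there. Cells that make Sftpc, carried over alone, would bring at most 4.41% of the CD4 difference of RT1-A1, Lilrb3a, Kbtbd11 and Socs3, if all whole-lung transcripts came from them in both genotypes. For the other falls such cells cannot be told apart, since the ceiling has a median of 88.0% over the 16 genes (quartiles 9.96% to 154%) and the part these cells make is unknown. A strain difference around the RT1 genes may add to the overlap and stays open. RT1 genes themselves were left out of its tests, and 3 of them are shared. RT1-CE1 and RT1-CE10 were higher and RT1-A1 lower in both, but reads can be divided among these near copies. Of the other 25 shared genes matched by symbol, 2 lie near RT1, Vps52 and Slc26a8 (one-sided Fisher's exact p = 0.0305). Of all tested non-RT1 genes there, 7.26% were called against 7.68% elsewhere (one-sided Fisher's exact p = 0.618, run before the narrower test).

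For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 300 genes in day 7 lung, where the highest of the others called 3, and 1 split in 10 gave as many. The values were 2 and 2 in day 56 lung (3 splits as large), 1 and 1 in spleen (3 splits) and 2048 and 0 for the days in WT (1 split). For lists they were 12 and 14 in day 7 lung (4 splits), 13 and 23 in day 56 lung (3 splits) and 10 and 8 in spleen (1 split). The 3 spleen splits that part all 3 mice in another way called 0 genes each and 6, 1 and 4 lists. For the interaction 40 splits were fitted, the real one included, and since its count is 0, which any split reaches, they do not test it. The highest of the others called 211 genes and points to a structure of the samples, since it equals the genotype effect averaged over both days.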

How the results depend on the processing

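The alternatives were set before the data were examined except for the removal of 58 table-specific genes and the averaged genotype effect, which were chosen after seeing the data. Over all values compared, 1838 kept their direction and side of the threshold (counts within 1.5 times), 290 lost a call and 50 gained one. A further 70 counts or values moved, among them log2 fold changes that changed sign in genes called in neither fit. Of the genes called in either fit, 0 reversed. Among the added ones 7 stayed and 7 moved. The cause of each change below was not tested unless stated.

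DESeq2 called 551 genes in day 7 lung (300 by edgeR), 178 in day 56 lung (2), 2 in spleen (1) and 48 in the interaction (0). Limma-voom called 4 in day 56 lung and 0 in spleen. Without a filter on low counts 7 genes were called in day 56 lung. Asking for a log2 fold change of at least 1 left 104 genes in day 7 lung, 256 of 784 in CD4 cells and 771 of 2048 between the days, by construction. RLE size factors and a mean of at least 5 CPM kept every count of called genes within 1.5 times.

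With an estimated correlation 0 lists passed in each of the 4 comparisons (12, 13, 19 and 10 with the preset one), and fry passed 1 in day 7 lung, 0 in day 56 lung, 3 in CD4 cells and 0 in spleen.

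The shared calls of day 7 and day 56 lung went from 0 to 16 higher and 23 lower with DESeq2, and to 38 and 37 at an unadjusted p under 0.01 (opposite: 0, 0 and 1). Those of day 7 lung and CD4 cells went from 17 higher and 16 lower to 33 and 28 with DESeq2, and to 46 and 49 at an unadjusted p under 0.01 (opposite: 13, 26 and 53). Those of day 56 lung and CD4 cells went from 0 to 6 and 5 with DESeq2, and to 13 and 13 (opposite: 0, 8 and 19).

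Leaving out 1 library at a time gave 94 to 372 called genes in day 7 lung, 1 to 1268 in day 56 lung, 76 to 970 in CD4 cells and 0 to 1 in spleen. The range was 0 to 597 for the interaction and 1235 to 3656 between the days. Called lists ran from 10 to 14, 4 to 17, 16 to 19 and 8 to 12 in the same order. The genotype effect averaged over both days gave 69 to 1880 called genes, against 211 with all libraries. The highest counts in day 56 lung, the interaction, the days and the average all came without WT day 56 library 3. In CD4 cells the remaining library of a group is assumed to vary like the other pair.

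With the replicate number as a block, 543 genes were called in day 7 lung, 0 in day 56 lung, 1084 in CD4 cells and 1 in the interaction. These rats share a number but no animal by their labels. Same-numbered libraries did not always correlate best (0.08, 0.13 and 0.32 at day 7, -0.21, -0.10 and -0.01 at day 56, 0.02 in CD4 cells). In spleen, where the numbers pair fractions of 1 mouse, the block gave 3 genes and 9 lists. It changed no other list call there than that of Th17. The days in WT are different groups of rats, and their numbers were not used as a block.

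Without the 58 genes the interaction stayed at 0 calls and the days gave 1966. Depth limits Il6 itself, which had at most 11 counts in whole lung.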

Other observations

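The averaged effect below was chosen only after the splits of the interaction had been seen, and it is a description of the same libraries.

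Averaged over day 7 and day 56 lung, 211 of 13865 genes differed between IL6KO and WT in edgeR, 87 higher and 124 lower, of which 107 were also called at day 7 alone. In 154 of them the 3 WT and 3 IL6KO libraries did not overlap on either day, which the choice of called genes favours. With CPM scaled over all 12 lung libraries, which differ from those scaled within a day, Adamts13 was lower on both days, from 17.4 ± 1.22 to 1.29 ± 0.482 CPM at day 7 and from 17.3 ± 7.37 to 2.22 ± 0.201 CPM at day 56 (SD, n = 3 each, averaged log2 fold change -3.35, SE 0.21, adjusted p = 2.57e-05). Slpi fell by 3.22 (SE 0.34, adjusted p = 0.00189) and Retsat, a retinol saturase gene, by 0.99 (SE 0.075, adjusted p = 9.91e-05). The BMP antagonist gene Grem1 fell by 1.41 (SE 0.29, adjusted p = 0.0365) and the chemokine gene Ccl24 by 0.93 (SE 0.16). Higher were C5 by 3.28 (SE 0.55, adjusted p = 0.0273), Prox2 by 2.70 (SE 0.22), Gstt3, a glutathione transferase gene, by 1.30 (SE 0.11, adjusted p = 0.000290), C3 by 0.63 (SE 0.094) and the platelet tubulin gene Tubb1 by 1.71 (SE 0.30). Lists with at least 2 of these were Th1 and cytotoxic genes (3 of 16 higher), platelet (2 of 13 higher), airway (2 of 18 higher), extracellular matrix (2 of 30 lower), chemokines (2 of 33 lower), macrophage (1 of 24 higher, 2 lower) and acute phase genes (1 of 14 higher, 1 lower). Adjusted over the list alone, 18 of 28 proliferation genes and 9 of 20 smooth muscle genes were lower. Ephx2 was called (-2.60, SE 0.40) although WT library 3 at day 7, at 1.36 CPM, lay within the IL6KO range of 1.19 to 2.11 CPM. Without WT day 56 library 3 the count was 1880, without IL6KO day 56 library 3 it was 101, without WT day 7 library 2 or 3 it was 69 and 84, and without IL6KO day 7 library 1, 2 or 3 it was 76, 85 and 102.

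Of the 33 genes called in the same direction in day 7 lung and CD4 cells, 29 had that direction at day 56 in lung, 7 of them with an unadjusted p under 0.05. C5 varied between WT lungs at day 56, at 3.07, 36.7 and 38.1 CPM in the fit of all 12 lung libraries.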
